A study of Equus caballus with 24 samples.

How the data were processed

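Messenger RNA was sequenced from skeletal muscle of the right leg and from carotid blood of 6 Thoroughbred horses, each sampled before and after exercise, which gave 24 libraries in 4 groups of 6. Per the labels' protocols, total RNA was checked for integrity, poly(A) RNA was selected with oligo-dT beads, fragmented and randomly primed, and the cDNA was ligated to adaptors and amplified. BWA, Picard and Cufflinks 1.3.0 are named per the submitters' processing notes, which give no order or role in the sources used here. The genome build and the annotation release are not given in the sources used here, so coordinates are those listed in the deposited files, counted from 1.

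Each library came with a table of 26954 genes and a table of 29153 transcripts. The authors deposited gene and transcript levels in FPKM (fragment numbers scaled by transcript length and library size) with confidence bounds in FPKM, and the deposited transcript tables add transcript length and read coverage. The sum of transcript FPKM matched the gene FPKM to a relative difference of at most 9.22e-06. In each library 10 to 16 genes had a status other than OK, and such genes were left out of the comparison concerned. FPKM is not a count, and the number of reads per library is not given in the files. The median ratio of coverage to FPKM over transcripts of at least 2000 bases, a rough measure of relative depth, spanned 3.91 to 4.30 in muscle and 3.02 to 3.61 in blood. FPKM of short transcripts was unstable: the highest listed value, 135249000 FPKM, belonged to a gene of 117 bases. The files list genes by Ensembl identifier and do not pair the identifiers with names. The 26 gene lists fixed before the data were examined, and the part of the naming rule that uses them, were therefore not applied.

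Within each tissue the deposited FPKM values were divided by a median-of-ratios factor per library, taken over genes with an FPKM of at least 1 in all 12 libraries. Factors spanned 0.727 to 1.22 in muscle and 0.901 to 1.12 in blood. For comparisons across tissues 1 further factor set the muscle and blood libraries to a common scale. Genes with a mean scaled FPKM of at least 1 were kept, in each tissue separately for the difference of effects. Tests used limma 3.58.1 in R 4.3.3 on log2(scaled FPKM + 1) with a variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Between the tissues a log2 difference of at least 1 was also required. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The comparisons were after against before exercise in muscle and in blood, the difference between those effects, muscle against blood before exercise, and the overlap of exercise calls by Fisher's exact test. No block was fitted in the main design, because no label states the submitters' model. The main counts, and the fits that leave out a horse, therefore do not use the pairing by horse.

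The labels give the same horse at both times, so the libraries are paired by animal, and a fit with the horse as a block was also run. As a check, deviations from the group mean correlated within a horse at 0.10 to 0.36 in muscle, where 6 of 6 horses matched best with their own library. In blood they correlated at -0.02 to 0.45, and horse F2 did not match best with its own.

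Identifiers named in the text follow the rule fixed before the data were examined, with its requirement of a gene symbol dropped: the largest changes past the threshold and, for exercise, in the same direction in at least 5 of 6 horses, limited to 2 each way per comparison. One gene lower in blood was named after its values were seen. The test was checked on simulated data with 200 changed genes per comparison. Some changed genes fell below the filter, so shares are given of all changed genes, with calls by the adjusted p alone. In the muscle simulation, run on 8762 genes, 22 of 67 genes changed 1.5-fold (32.8%), 44 of 67 changed 2-fold (65.7%) and 54 of 66 changed 4-fold (81.8%) were recovered, with 62, 64 and 57 of them past the filter. In the blood simulation, run on 10281 genes, the shares were 56.7%, 80.6% and 81.8%, with 67, 64 and 55 genes past the filter. For the difference between tissues in the effect of exercise, run on 8845 genes, they were 14.9%, 62.7% and 87.9%, with 67, 63 and 60 past the filter. For muscle against blood, run on 11332 genes, they were 41.8%, 83.6% and 90.9%, with 65, 64 and 61 past the filter. Of the simulated calls, 6.98% in muscle, 6.41% in blood, 2.65% for the difference of effects and 7.69% between the tissues were false. The simulated noise was independent between genes and held no horse effect, so these shares need not hold for the real data. Other settings, listed before the data were examined, were a pseudocount of 0.1, no filter on low values, FPKM as deposited, quantile normalization, the horse as a block alone and with either of those scalings, no variance trend, all statuses kept, and leaving out each horse in turn. Settings added after seeing the data left out the blood library of horse S2 after exercise, the muscle library of horse F3 after exercise, or genes with transcripts under 300 bases.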

Results

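Transcript levels were measured by poly(A) RNA sequencing in skeletal muscle and blood of 6 Thoroughbred horses before and after exercise. The horses carry the labels F1, F2, F3, S1, S2 and S3. F1, F2, F3 and S1 are male and S2 and S3 female, and the labels do not explain the letters. Each of the 4 groups held 6 libraries from separate animals. No group without exercise was sampled, so a change after exercise cannot be told apart from one of time or repeated sampling. The muscle libraries listed 13347 to 13997 genes above 0 and the blood libraries 13474 to 14464. The number of reads is unknown, so no counting interval can be given. The 10 most abundant transcripts of at least 300 bases made up 24.3% to 30.7% of the summed coverage in muscle and 6.95% to 9.82% in blood. A search for genes above 1 FPKM in every library of 1 labelled sex and below it in every library of the other found 1 gene, on chromosome 4 (50306243 to 50307660). It was listed at 2.31 to 9.25 FPKM in the 16 libraries from males and at 0 to 0.785 FPKM in the 8 from females. It was picked with the labels, so it is no check of them.

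The first comparison asked which transcripts changed in muscle with exercise. Of the genes named by the fixed rule, ENSECAG00000023949 (chromosome 11, 38519577 to 38594301) rose from 1.84 ± 1.72 to 275.6 ± 208.7 scaled FPKM (SD, n = 6). Its log2 fold change was 6.39 ± 0.50 (SE; limma adjusted p = 2.73e-06), with a rise in 6 of 6 horses. ENSECAG00000024172 (chromosome 5, 35867217 to 35874672) rose from 0.0914 ± 0.0427 to 82.9 ± 55.9 scaled FPKM, a log2 fold change of 5.91 ± 0.45, again in 6 of 6 horses. ENSECAG00000024973 (chromosome 5, 30168731 to 30190325) went from 41.4 ± 10.8 to 11.7 ± 5.37 scaled FPKM, with a log2 fold change of -1.82 ± 0.27 and an adjusted p of 4.20e-04. ENSECAG00000011609 (chromosome 16, 5091232 to 5097179) went from 12.1 ± 6.62 to 3.13 ± 2.70 scaled FPKM, with a log2 fold change of -1.76 ± 0.41 and an adjusted p of 0.00798. Both were lower in 6 of 6 horses. The order within each pair held with a pseudocount of 1. With 0.1 the log2 fold changes were 7.08 for ENSECAG00000023949, 8.42 for ENSECAG00000024172, -1.91 for ENSECAG00000024973 and -2.22 for ENSECAG00000011609.

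Of 9012 genes tested in muscle, 1338 were higher and 681 lower after exercise. The rises were larger than the falls: the median log2 fold change was 0.96 among the higher genes and -0.57 among the lower ones. At least a 2-fold change was seen in 640 higher and 58 lower genes, and at least a 16-fold change in 38 higher genes and 0 lower ones. With the horse as a block, 1622 genes were higher and 1346 lower. In fits without the block, the number of lower genes was 402 without F1, 359 without F2, 372 without S1 and 383 without S3. The balance of directions depended on the scaling. Of the calls, 66.3% were higher under the main scaling, 33.8% with FPKM as deposited and 49.4% with quantile normalization, and the median log2 fold change of all genes was -0.06, -0.28 and -0.14 in that order.

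**Figure D1:**
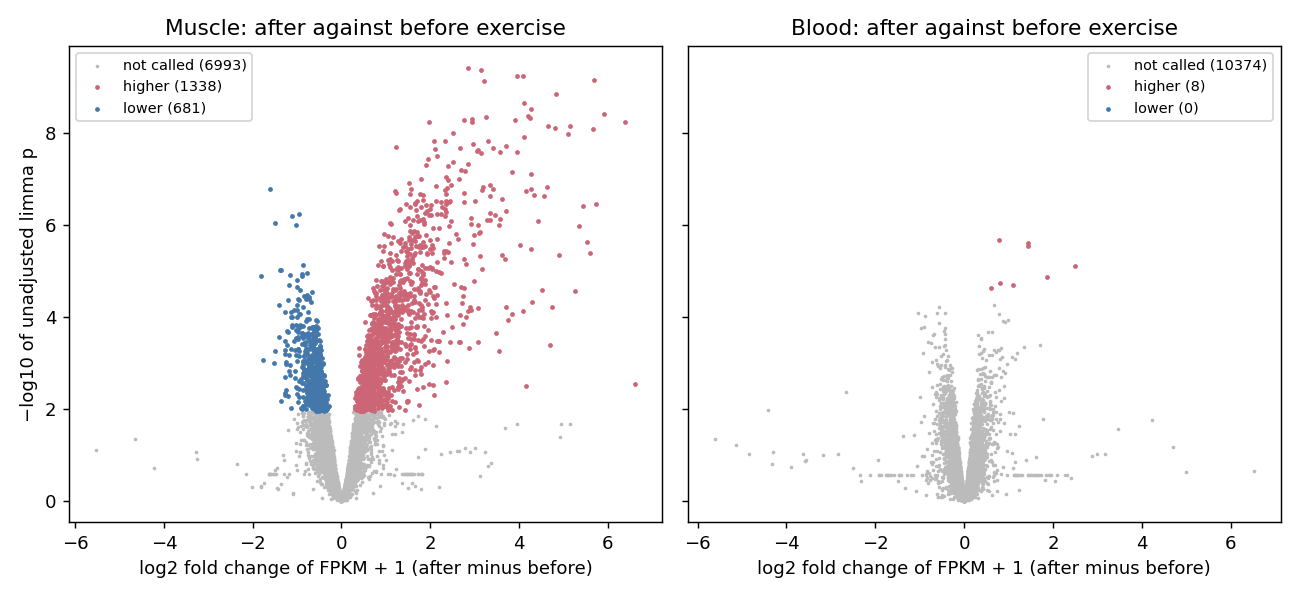
Unadjusted limma p on a −log10 scale against the log2 fold change of FPKM + 1 after exercise, 1 point per gene tested, for muscle (left) and blood (right), 6 horses at each time. Coloured points passed the adjusted threshold: 1338 higher and 681 lower genes in muscle and 8 higher genes in blood.

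The libraries separated by exercise in muscle more than in blood. On the first principal component of muscle, with 40.1% of the variance, the 6 libraries before exercise scored -40.6 to -29.0. After exercise F1, F2, S1 and S3 scored 40.6 to 53.4, S2 scored 15.6 and F3 scored -1.23. In blood the first component held 18.0% of the variance, and the 2 times overlapped on it. On the second component of blood, with 13.2% of the variance, the score after minus that before exercise was negative in 6 of 6 horses, from -37.9 to -3.10 (exact sign-flip permutation test, two-sided, p = 0.0313, the smallest the design allows; adjusted over 4 component tests p = 0.0625). The median correlation between libraries at different times was 0.863 in muscle and 0.936 in blood, across genes.

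**Figure D2:**
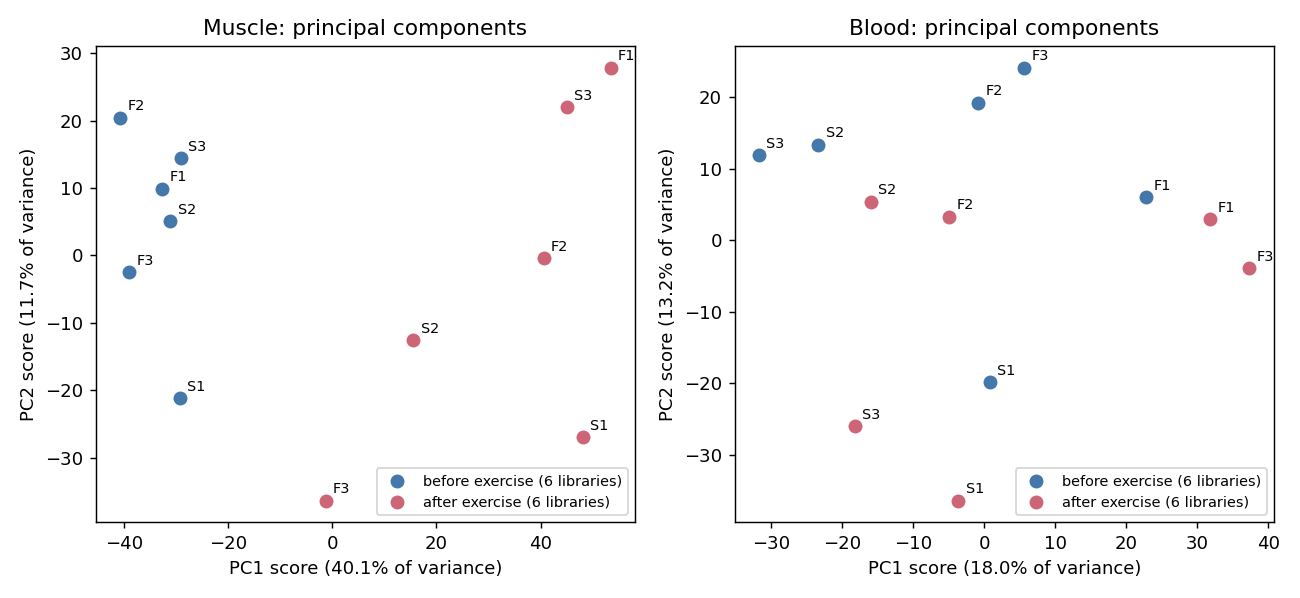
Scores of the 12 muscle libraries (left) and the 12 blood libraries (right) on the first 2 principal components, labelled by horse and coloured by time. In muscle all 6 libraries after exercise lie at higher first-component scores than the 6 before, with F3 at -1.23 and S2 at 15.6 nearest to them.

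The second comparison asked the same of blood. ENSECAG00000014260 (chromosome 24, 20677112 to 20679718) rose from 104.3 ± 48.2 to 604.7 ± 316.3 scaled FPKM (SD, n = 6), a log2 fold change of 2.49 ± 0.35 (SE) with a limma adjusted p of 0.0198. ENSECAG00000018002 (chromosome 10, 15991321 to 15996022) rose from 1.10 ± 1.06 to 6.37 ± 2.46 scaled FPKM, a log2 fold change of 1.87 ± 0.28 with an adjusted p of 0.0281. Both were higher in 6 of 6 horses. They also rose in muscle, with log2 fold changes of 4.83 and 3.91. Without the filter on low values their adjusted p in blood was 0.0526 and 0.0587. Without F1, F2, F3, S1 or S2 neither passed, with adjusted p of 0.0598 to 0.116 for ENSECAG00000014260 and 0.0863 to 0.149 for ENSECAG00000018002. Their log2 fold changes in those fits stayed at 2.34 to 2.56 and 1.71 to 1.88. Of 10382 genes tested in blood, these and 6 others were higher, with log2 fold changes of 0.60 to 2.49, each in all 6 horses. By limma 0 genes were lower, against 898 genes in either direction at an unadjusted p under 0.05.

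With the horse as a block, 58 genes were higher and 53 lower in blood. The lower gene with the smallest p in that fit, named after its values were seen, was ENSECAG00000004913 (chromosome 17, 22611148 to 22613104). It went from 5.86 ± 1.54 to 2.37 ± 0.92 scaled FPKM, lower in 6 of 6 horses, with a log2 fold change of -1.04 and an adjusted p of 0.00224 with the block and 0.0636 without it. Without a block it also passed with FPKM as deposited (0.0404), without F3 (0.0457) and with short transcripts left out (0.0474). The count of higher genes without a block fell whichever horse was left out: it was 2 without F1, 2 without F2, 3 without F3, 5 without S3, and 0 without S1 or without S2. No horse was left out of the fit with the block, so its counts were not tried in this way. Leaving out only the blood library of S2 after exercise, a setting added after seeing the data, gave 9 higher genes without a block. In that fit ENSECAG00000014260 and ENSECAG00000018002 had limma adjusted p of 0.0193 and 0.0437. Of the blood calls, 100% were higher under the main scaling and 50% with FPKM as deposited.

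**Figure D3:**
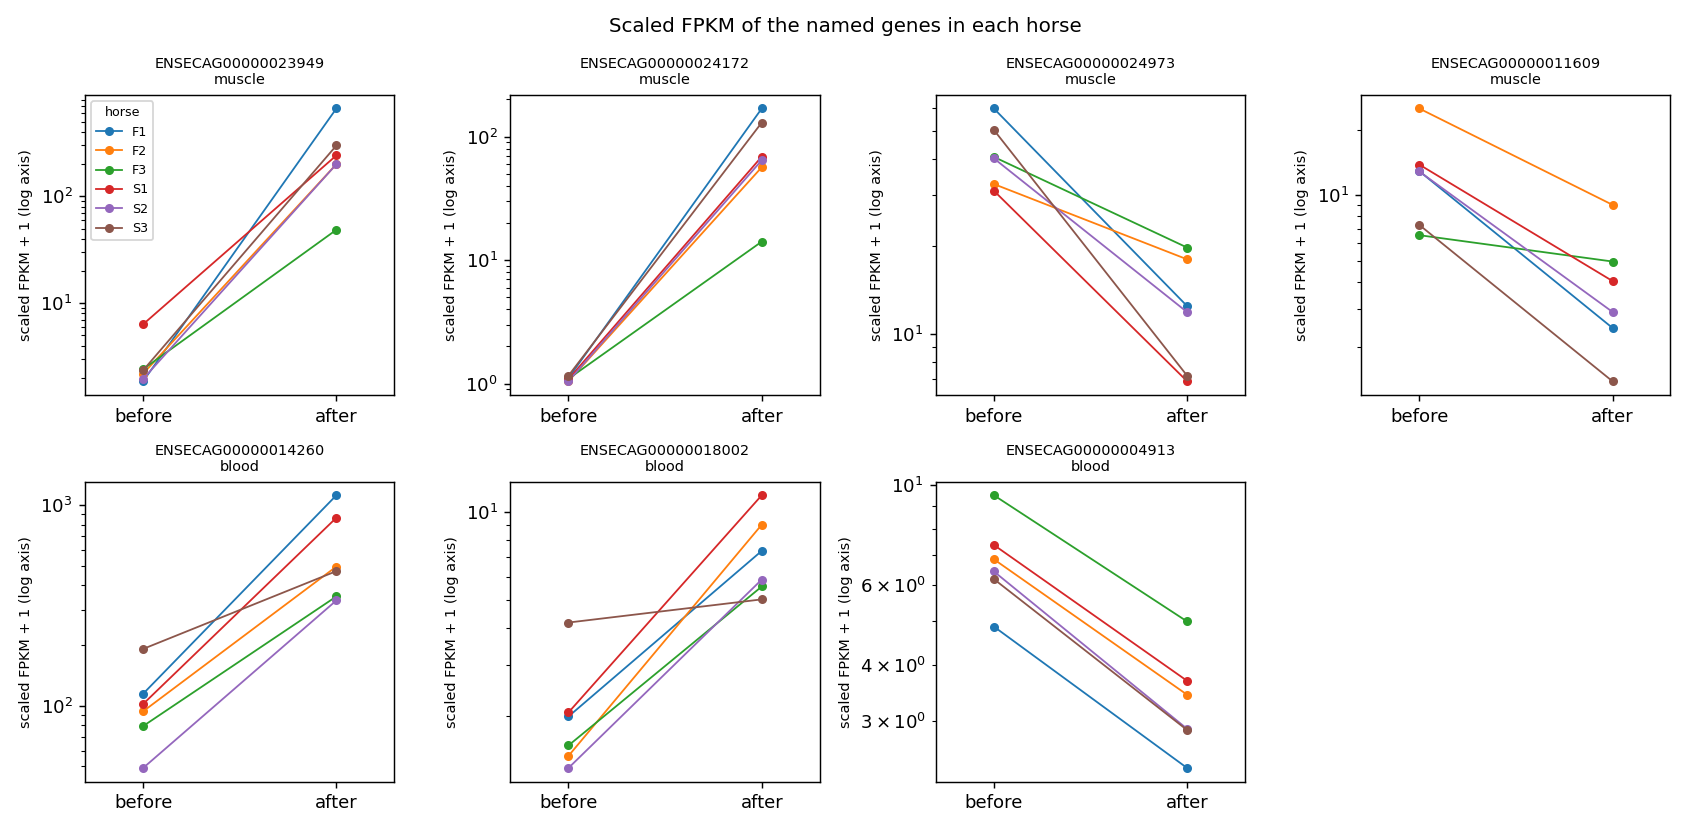
Scaled FPKM + 1 on a log axis before and after exercise for 4 genes in muscle and 3 in blood, with 1 line per horse. Each line runs in the same direction within a panel, and ENSECAG00000004913, lower in blood, had an adjusted p of 0.0636 in the main fit and 0.00224 with the horse as a block.

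Calls in the 2 tissues overlapped in the upward direction. Of 7775 genes tested in both, 1137 were higher in muscle and 8 in blood, and 6 were higher in both, where independent lists would share 1.17 (Fisher's exact test, two-sided, p = 2.08e-04). With the horse as a block 22 genes were shared, where independent lists would share 7.03. In the downward direction with the block 2 genes were shared, where independent lists would share 2.80 (Fisher's exact p = 1), and 5 of the 21 genes lower in blood were higher in muscle. In fits without the block, the upward overlap was 2 genes without F3 (Fisher's exact p = 0.0646). It was 0 without S1 or without S2, since no blood gene passed. Fisher's test counts genes as independent units, so its p does not measure the variation between horses.

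The third comparison tested whether the effect of exercise differed between the tissues. ENSECAG00000004107 (chromosome 1, 60151732 to 60153042) went from 68.3 ± 40.7 to 24.5 ± 8.94 scaled FPKM in muscle and from 22.1 ± 7.16 to 44.6 ± 16.7 in blood (SD, n = 6). The difference of its log2 changes was -2.21 ± 0.54 (SE; limma adjusted p = 0.00641), and without S3 its adjusted p was 0.0525. ENSECAG00000013541 (chromosome 27, 16180345 to 16181954) went from 7.31 ± 1.86 to 1.51 ± 1.25 in muscle and from 22.8 ± 5.62 to 27.2 ± 9.78 in blood, a difference of -2.03 ± 0.37. The 2 genes named for a more positive change in muscle were ENSECAG00000025403 (chromosome 7, 53419974 to 53420104) and ENSECAG00000015141 (chromosome 8, 6719232 to 6720195), whose transcripts have 131 and 219 bases. Values of such short transcripts were unstable. ENSECAG00000025403 was listed at 0 in all muscle libraries before exercise and at 0 to 5343 scaled FPKM after it, so no fold is given. Its adjusted p of 0.0165 became 0.0950 without F2, 0.0810 without F3 and 0.0572 without S1. ENSECAG00000015141 was listed at 2.16 ± 3.07 scaled FPKM in blood before exercise and at 0 in all blood libraries after it. In muscle it was at 0 to 5.59 before exercise and 0 to 507 after it. It fell below the filter without S2 or without S3.

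Of 8922 genes tested, 885 had a more positive change in muscle than in blood and 283 a more negative one. With the horse as a block within each tissue the counts were 1290 and 755. Without S1 the total fell from 1168 to 738 genes, and with FPKM as deposited it was 667.

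Before exercise the tissues differed in most genes tested. ENSECAG00000019728 (chromosome 22, 34799688 to 34800907) reached 58870 ± 10138 scaled FPKM in muscle and 3.03 ± 3.81 in blood (SD, n = 6), and ENSECAG00000022433 (chromosome 10, 15881172 to 15890008) reached 32911 ± 5652 in muscle and 1.65 ± 2.74 in blood. Their log2 differences were 14.43 ± 0.49 and 14.19 ± 0.47 (SE; limma adjusted p of 1.96e-12 and 1.47e-12). The 2 genes named for a higher level in blood were ENSECAG00000025519 (chromosome 4, 15611076 to 15611207) and ENSECAG00000025403, with transcripts of 132 and 131 bases. Both were listed at 0 in the 6 muscle libraries before exercise and at 0 in at least 1 blood library, so no fold is given. Of 11479 genes, 3057 were at least 2-fold higher in muscle and 3706 at least 2-fold higher in blood.

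Genes were also grouped, after seeing the data, by their mean level in the 2 tissues over all 24 libraries. Of 215 genes at least 16-fold higher in blood that were tested in muscle, 96 were higher and 1 lower in muscle after exercise. In blood 493 genes of this class were tested. The muscle counts cover only genes past the filter there, which uses the mean over both times, so a change could decide entry for genes near 0. Of 522 genes at least 16-fold higher in muscle, 54 were higher and 56 lower under the main scaling, 36 and 127 with FPKM as deposited, 52 and 88 with quantile normalization, and 66 and 125 with the horse as a block. In the first class these counts were 77 and 2, 91 and 2, and 131 and 2. Relative to the median of all genes, the median change of the first class was 0.86 ± 0.53 on the log2 scale (SD, n = 6), above 0 in 5 of 6 horses (exact sign-flip permutation test, two-sided, p = 0.0625, adjusted over 10 class tests p = 0.156, where 0.0313 is the smallest unadjusted p the design allows). With FPKM as deposited and with quantile normalization it was above 0 in 6 of 6 horses, with an exact p of 0.0313 each. The median of genes 4-fold to 16-fold higher in blood was 0.20 ± 0.13 above that of all genes, in 6 of 6 horses (exact p = 0.0313, adjusted p = 0.156). The median level in muscle of 322 genes abundant in blood, as a percent of the level in blood of the same horse and time, was 0.849% to 1.47% before exercise. After exercise it was 4.90% in F2, 3.93% in F1, 3.90% in S1, 2.84% in S3, 1.86% in S2 and 0.656% in F3.

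**Figure D4:**
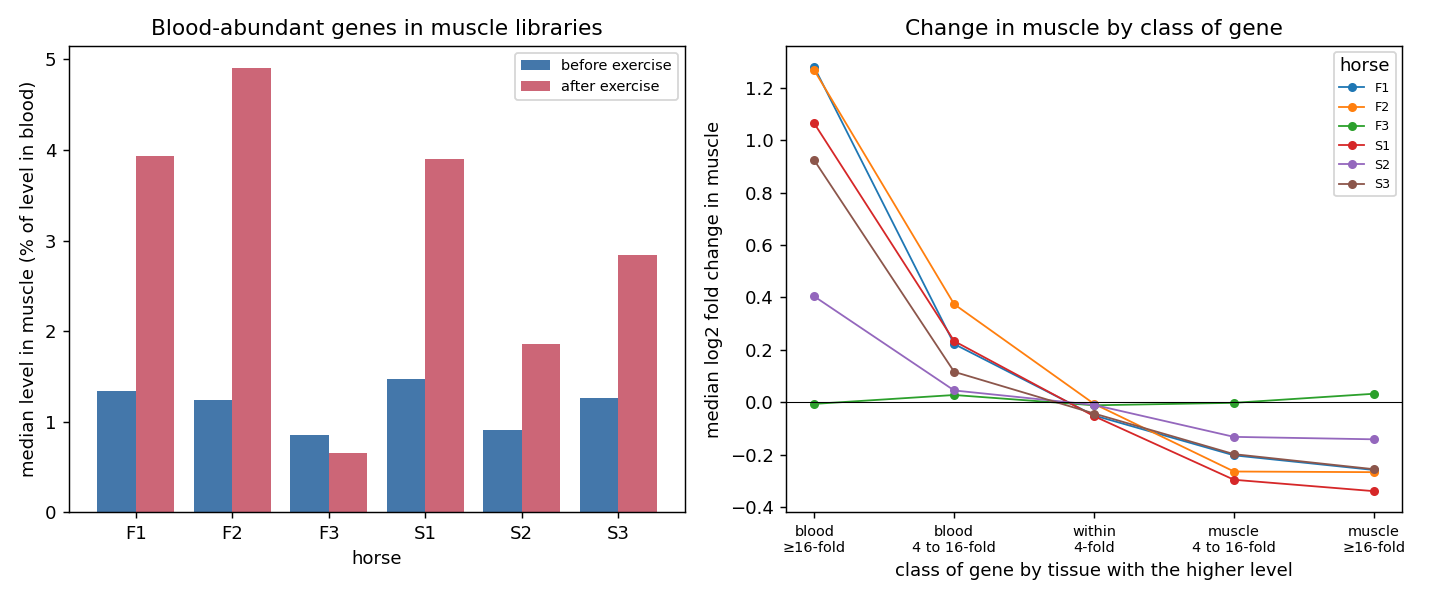
Left, the median level in muscle of 322 genes abundant in blood, as a percent of their level in blood of the same horse and time, before and after exercise. Right, the median log2 fold change in muscle of genes grouped by the tissue with the higher level, 1 line per horse. The blood-abundant genes lie at 0.656% in F3 and at 1.86% to 4.90% in the other 5 horses after exercise.

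The change with exercise was also compared between the 2 female and 4 male horses. By limma 0 genes differed in muscle or in blood, against 343 of 9012 and 462 of 10382 genes at an unadjusted p under 0.05. Both counts are below what chance alone gives at that threshold, and with 2 females a difference could be missed. The letters F and S in the labels divide the horses partly along sex and were not tested apart from it.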

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

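The tests in this part on blood RNA in muscle, on the blood library of S2 and on horse F3 were chosen after the results were seen; the counts over other splits were planned. Across 42 checks for a library standing apart from the other 5 of its group, 8 passed the threshold, where chance gives about 2.1. Each value is the gap to the nearest library divided by the range.

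In blood after exercise the library of S2 stood apart in 3 measures. It listed 14464 genes above 0, with 13632 in the next library (0.840). Its ratio of coverage to FPKM was the lowest, at 3.02 against 3.43 (0.749). Muscle-abundant genes had a median level of 0.223% of muscle, against 0.130% in the next library (0.665). In it 181 genes were at least 2-fold above all other blood libraries, while the other blood libraries had 6 to 27 such genes. The values argue against muscle RNA as the source: the extra muscle share gave 50% or more of the excess for 1 of the 181 genes. The 181 genes were picked as at least 2-fold above all other blood libraries, male ones included. Their excess over male blood was thus fixed by the choice and decides nothing about RNA of a male horse. That explanation stays open. The gene on chromosome 4 found by the search across labelled sexes was listed at 0.785 FPKM there, 10.7% of its mean in male blood, and at up to 0.0760 FPKM in the other female libraries, but 1 gene cannot settle it. No biological explanation was tested.

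Genes abundant in blood were higher in muscle after exercise in 5 of 6 horses, as given with the tissue classes. Whole blood in the muscle sample would raise these genes by 1 common share. Of the 50 most abundant, 8 lay below the median increase of their horse in all 6 horses and 13 above it in all 6. Chance gives 0.781 of each if the side is independent in each horse. The smallest increase was -0.227%. A steady difference of a gene between the libraries of the tissues would repeat in every horse even under 1 common share. The counts therefore cannot decide whether 1 common share of whole blood was the whole cause or a part of it. Some kinds of blood cell, entering the muscle or held in its vessels, may also account for the rise of these genes. Increases reached 10.8% of the blood level, and without gene names no cell markers could be tested. For the muscle response as a whole, 78.4% of the higher calls stayed after blood of the same horse was subtracted at the 90th percentile share, so blood RNA was not the whole source. In the class at least 16-fold higher in blood, 13 of 94 calls stayed at that share and 52 at the median share.

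Horse F3 showed the smallest change in muscle. A swap of its labels is argued against by the library labelled before, which scored -36.0 on the first component of genes outside the blood classes, within the -37.8 to -25.9 of the other horses. A library taken before exercise is argued against as well: of 1389 genes called higher in the other 5 horses and also tested in all 6, 82.3% were higher in F3, against 39.0% to 60.5% between pairs of libraries before exercise. Response size and the rise in the blood share were related over the 6 horses by Pearson's r = 0.849 (exact permutation p = 0.0208; 0.852 without F2 and F3) but not clearly by Spearman's rho = 0.60 (exact permutation p = 0.242), so whether they move together stays open. The library of F3 after exercise had the lowest scaling factor in muscle, 0.727, and the fewest genes above 0, 13347. The library of S3 after exercise was close, at 0.792 and 13402. Whether such traits of the library bear on the small change was not tested. A weaker response of horse F3 is a hypothesis left untested.

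The remaining libraries standing apart are given as values. In muscle before exercise S3 had the fewest genes at 1 FPKM or more, 8240 against 8827 in the next (0.686), and the lowest scaling factor, 0.90 against 1.13 (0.711). ENSECAG00000023949 was highest in S1 in muscle before exercise, at 5.33 scaled FPKM against 1.40 (0.877). ENSECAG00000018002 was highest in S3 in blood before exercise, at 3.18 against 1.06 (0.744). The 10 most abundant transcripts held 9.82% of coverage in S3 in blood after exercise, against 7.63% (0.765).

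The effect of exercise differed between muscle and blood in 1168 genes by the test of the difference. Among the named genes the adjusted p of that limma test was 0.0165 for ENSECAG00000025403 (0.0572 to 0.0950 without S1, F3 or F2). For ENSECAG00000015141 it was 0.00160, and this gene fell below the filter without S2 or without S3. By the same test the adjusted p was 0.00641 for ENSECAG00000004107 and 5.29e-04 for ENSECAG00000013541. In the transcript tables, whose FPKM the other comparisons do not test, each transcript was set against the other transcripts of its gene. The value tested was the log2 ratio of their scaled FPKM, with 1 added to each. It changed for 4 of 472 transcripts in muscle and for 0 of 784 in blood by limma. At an unadjusted p under 0.05 there were 49 and 50, and with the horse as a block 1 and 0 passed. With 1 added, the ratio of low transcripts can also move with the level of the whole gene.

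Other splits of the libraries were fitted in the same way. For exercise within a tissue, the larger direction of each other split was counted. In muscle, 1 of 100 splits of the 12 libraries gave as many genes as the 1338 higher ones, the real split itself. The highest other gave 726. As many as the 681 lower ones came from 2 of 100, the real split and that highest other. The latter set F1 before exercise and F1, F2, S1, S2 and S3 after exercise against the rest. It thus largely parted the times, so its 726 genes are not a count free of the change with exercise. Among the 32 splits that part every pair, 1 reached 1338 and 1 reached 681, with 598 in the highest other. With the block, 1 reached 1622 and 1 reached 1346, with 0 in the highest other. Chance is thus unlikely as the source of the muscle counts, but so few splits cannot exclude it. In blood, 2 of 100 splits gave at least the 8 higher genes, and the highest other gave 44, several times the real count. That split set both libraries of F1, F3 and S1 against both libraries of the other 3 horses, so it parted horses and not times. Among splits parting every pair 1 reached 8, with 1 in the highest other. With the block 1 reached 58 and 1 reached 53, with 2 in the highest other. For the 0 lower genes in blood without a block the comparison says nothing, since every split, 100 of 100 and 32 of 32, gives at least 0 genes. For the 1168 genes with different effects 1 of 100 regroupings reached that count (911 in the highest other). These regroupings took away the change with exercise in both tissues and ignored the pairing. They therefore cannot tell whether the effects differ between the tissues. For the 6763 genes differing between tissues 1 of 100 splits reached that count (4668 in the highest other), which makes chance unlikely there. For the overlap of 6 genes 1 of 100 did, with 0 in the highest other, but only 2 of the other 99 regroupings had enough higher genes in blood to reach it, so this comparison decides nothing.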

How the results depend on the processing

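The numbers of genes differing between the tissues before exercise stayed within 1.5 times under every alternative run, and the number higher in muscle under all but one: 793 with FPKM as deposited. With FPKM as deposited 1553 genes were lower in muscle, 8 lower in blood and 667 differed in effect between tissues. With quantile normalization 1211 were lower in muscle and 1 lower in blood. With the replicate block, pairing by horse, 1346 were lower in muscle, 58 higher and 53 lower in blood and 2045 differed in effect, and the overlap was 22 genes. With the block and FPKM as deposited 2871 were lower in muscle and 31 higher and 60 lower in blood. With the block and quantile normalization 2230 were lower in muscle, 49 higher and 54 lower in blood, and 2563 differed in effect. The overlap was 14 and 20 genes with the block and those scalings, in that order. Without the filter 4 genes were higher in blood. Without the variance trend 1 was lower in blood. Chosen after seeing the data, leaving out the blood library of S2 after exercise gave 9 higher and 1 lower in blood. Leaving out transcripts under 300 bases, also chosen then, gave 9 higher and 2 lower. The cause was not tested.

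Leaving out each horse in turn, without a block, gave 986 to 1418 higher and 359 to 649 lower genes in muscle and 0 to 5 higher and 0 to 1 lower genes in blood. It also gave 738 to 1273 genes differing in effect and an overlap of 0 to 4 genes. Leaving out F3 raised the number higher in muscle to 1418 and the number differing in effect to 1273, and leaving out F3 or S3 gave 1 gene lower in blood. The cause was not tested.

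For 15 named differences, 249 alternative values were run: 227 kept their side of the threshold, 16 lost it, 6 gained it and 0 changed sign. The gene lists, and camera with an estimated correlation, were not run because the files do not pair identifiers with names. Read depth is unknown, so its effect on low genes cannot be given.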

Other observations

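The tests in this part were chosen after the data were seen. Along the chromosomes, genes lower in muscle after exercise lay next to each other more often than chance placement gives. Of 5642 pairs of neighbouring tested genes that do not overlap and lie within 100 kb, both were lower in 53, against a mean of 32.2 over 10000 permutations of the calls (permutation p = 2.00e-04, adjusted over both directions 4.00e-04). For the genes higher after exercise both members were called in 139 pairs, against a mean of 124.4 (permutation p = 0.0841, adjusted 0.0841). Genes are not independent replicates, and paralogs lying side by side were not removed.

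Of the 8 genes higher in blood, ENSECAG00000014260 and ENSECAG00000018002 changed more in muscle than in blood in the fit across tissues, by 2.41 ± 0.51 and 2.82 ± 0.47 on the log2 scale (SE; limma adjusted p of 0.00221 and 1.60e-04). In that fit muscle values are brought to the common scale before 1 is added, so these differences are not those of the fits within each tissue. In blood ENSECAG00000014260 stood at 104.3 ± 48.2 scaled FPKM before exercise (SD, n = 6), so its rise came on top of a high level there. ENSECAG00000018002 stood at 1.10 ± 1.06.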
